A study of Mus musculus with 8 samples.

How the data were processed

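Total RNA from mouse liver was hybridised to 8 Illumina bead arrays, 1 per sample. The labels give the strain as Balb/c and the age as 2 months, and they put the samples in 4 groups: wild-type vehicle (n = 1), knockout vehicle (n = 1), wild-type CCl4 (n = 3) and knockout CCl4 (n = 3). The knockout lacks the cytokine genes Il4 and Il13. Carbon tetrachloride (CCl4) is a solvent that cytochrome P450 enzymes turn into a radical, which kills hepatocytes around the central vein. Per the labels' protocols, RNA was purified with Trizol and a column and labelled as biotinylated cRNA. The scanner software and any background step were not given in the sources used here.

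The deposited raw table gives 1 summarised bead intensity per probe and array on a linear scale, without normalization between arrays. Beside each intensity, per the file headers, stands a detection p-value, which sets the probe against the array's negative control beads. The deposited value table of the series holds the same intensity minus 1 constant per array, from 48.6 to 56.8, with medians from 12.3 to 20.0; it was used only as an alternative, and the reason for the constant stays unknown. Its scale is linear and its direction is that of the raw intensities. Median raw intensities ran from 60.9 to 76.9, and 8899 to 9821 of the 25697 probes per array had a detection p-value under 0.01. On the CCl4 arrays the medians were 68.5 to 76.9 in wild type and 63.6 to 66.9 in the knockout, so all knockout CCl4 arrays were dimmer. The number of arrays limits the precision, with a median standard error (SE) of 0.17 on the log2 scale for the genotype difference after CCl4.

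Intensities were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3 (offset 16), with the negative controls inferred from the detection p-values. Probes were kept where the detection p-value was under 0.01 on every array of at least 1 group, which left 10128 probes. Gene symbols came from the platform annotation, which gives 1 symbol for 23978 probes, several for 0 and none listed for 1719. Of the probes with a symbol, 23962 matched the RefSeq gene table of GRCm38.p6 through Entrez identifiers, 16 kept the annotation's symbol, and 0 symbols needed updating. The genome build of the probe design was not given in the sources used here, so that table served only for names and neighbouring genes. The probe with the highest mean stood for each gene, giving 7257 genes. Of the 1732 genes with several tested probes, 0 had calls in opposite directions between genotypes and 6 did for CCl4 (Egfl7, Hsd3b2, Ikbkg, Ppp2r5e, Rab38 and Vmp1).

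Linear models with 4 group means were fitted to all 8 arrays with lmFit and eBayes, 2-sided, with Benjamini-Hochberg adjustment over the 7257 genes and a threshold of 0.05. The residual spread came from the 6 CCl4 arrays (4 degrees of freedom), and each lone vehicle array was assumed to vary like them. Nothing in the labels says that the arrays came from separate animals, so p-values measure only the spread between these samples, which may be technical. The contrasts were knockout minus wild type after CCl4, CCl4 minus vehicle as the mean of both genotypes and in each genotype, and the difference of these responses (interaction). The vehicle pair was compared without a test. For a probe not above background on any array of the lower group, a fold is given as a bound: the mean of the higher group over the mean of, per array, the higher of the lowest detected signal and the probe's own.

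Before the data were examined, 35 gene lists (1033 members, 903 of them on the array) were fixed; 32 had at least 3 measured genes. The lists for eosinophils, for mast cells and basophils, and for pancreas acinar cells had fewer and were not tested. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, with an estimated correlation and with fry as alternatives. Members past the threshold were counted over all genes and adjusted over the list alone. In the vehicle pair, each list's median was placed among 10000 random lists matched on mean expression.

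The genes named were also set beforehand. They were, per comparison, the 8 largest increases and 8 largest decreases among called genes whose arrays did not overlap (no such condition for the interaction), without predicted-gene names; the 2 to 4 members of a described list with the smallest p; and Il4, Il13 and the detected members of the type 2 list. Genes named outside this rule are said to be so.

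On simulated arrays with 200 changed genes among 7257, the genotype contrast called 91.0% of genes changed by 1 on the log2 scale and 20.9% of those changed by 0.5. The CCl4 contrast called 100% and 20.9%, that in wild type 58.2% and 1.49%, that in the knockout 64.2% and 4.48%, and the interaction 7.46% and 0%. Of genes changed by 2, the interaction called 95.5% and the other contrasts 100%. False calls made up 2.63% of calls between genotypes, 8% for CCl4, 6.84% in wild type, 7.94% in the knockout and 4.23% for the interaction. A simulated list of 30 genes shifted by -0.6 was called in every contrast. Unshifted lists were called in 1 of 31 cases for CCl4 in the knockout and in 0 of 31 in the other contrasts. The simulated genes varied independently, so these runs do not show how often lists of correlated genes are called falsely. They used the preset correlation only. How often a shifted list passes with an estimated correlation, on 4 residual degrees of freedom, was not measured.

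Alternatives were normexp with an offset of 50, no background correction, median scaling, the deposited value table with a floor of 16, no probe filter, another filter, all probes or the mean of a gene's probes, a trended robust eBayes, the replicate number as a block, each array left out, an additive model for CCl4, the CCl4 arrays on their own, and a minimum log2 difference of 1. Chip identity is not given by the files, so chip was not used as a block. Without 1 vehicle array the additive model was fitted, in which the CCl4 effect is then the response of the other genotype alone. Values given without the wild-type or the knockout vehicle array are therefore not means of both genotypes, and they also hold differences between genotypes.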

Results

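Gene expression was measured in liver of wild-type mice and of mice lacking Il4 and Il13, cytokine genes of type 2 immunity, after vehicle or CCl4. There were 3 arrays per genotype after CCl4 and 1 per genotype after vehicle, and 7257 genes were tested. Correlations of normalized log2 values across genes ran from 0.977 to 0.983 within wild-type CCl4 arrays and from 0.987 to 0.988 within knockout CCl4 arrays. They ran from 0.962 to 0.977 between the genotypes after CCl4 and from 0.891 to 0.923 between CCl4 and vehicle arrays, and the vehicle pair had 0.972. The first principal component held 59.8% of the variance and separated CCl4 from vehicle, and the second held 17.6% and separated the genotypes after CCl4.

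The targeted genes were read first, as a check of the labels. Neither Il4 nor Il13 was above background on any of the 8 arrays. The lowest detection p was 0.272 for Il4 and 0.0602 for Il13, with 1 probe each. Il4 intensities ran from 39.5 to 58.2 and Il13 intensities from 51.2 to 70.4. The probes therefore check nothing about the genotype of any array.

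CCl4 changed the expression of many liver genes, as the mean of both genotypes (6 CCl4 against 2 vehicle arrays). Genes of cell division rose: Birc5, a subunit of the chromosomal passenger complex, by 4.81 ± 0.20 on the log2 scale (SE), Cdc20, an activator of the anaphase-promoting complex, by 4.50 ± 0.19, and Stmn1, a microtubule-destabilising protein, by 4.43 ± 0.15. Among the largest decreases were those of the drug-metabolising P450 gene Cyp1a2 (-4.49 ± 0.79), the glutamate transporter gene Slc1a2 of pericentral hepatocytes (-4.33 ± 0.17, at least 10.3-fold) and the hepcidin gene Hamp2 (-4.62 ± 0.59). With a trended robust eBayes Cyp1a2 did not pass (adjusted p = 0.0535). In all, 1372 genes rose and 1351 fell (limma with Benjamini-Hochberg adjustment), 486 and 411 of them by at least 1 on the log2 scale. The deposited values, which moved the median change of all genes by 0.16, gave 1636 up and 783 down.

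Also among the largest increases were Ly6d (6.92 ± 0.29, at least 64.1-fold), the fetal liver gene Afp (5.97 ± 0.22, at least 28.4-fold) and the iron-binding acute phase gene Lcn2 (5.42 ± 0.20). The serine synthesis enzyme gene Psat1 rose by 5.30 ± 0.25 (at least 15.3-fold) and the immediate early gene Fos by 4.58 ± 0.64 (at least 11.5-fold). Ly6d, Afp, Psat1, Fos and Birc5 (at least 19.3-fold) were not well above background on the vehicle arrays, and Slc1a2 was not on the CCl4 arrays. Also among the largest decreases were the steroid enzyme gene Hsd3b5 (-4.35 ± 0.18), the methyltransferase gene Inmt (-4.17 ± 0.75), Sult2a8 (-3.88 ± 0.39), Ces3b (-3.87 ± 0.23) and Ugt3a1 (-3.68 ± 0.19). With a trended robust eBayes Inmt did not pass (adjusted p = 0.0566).

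Of 33 measured genes of the G2/M and mitosis list, 31 rose and 0 fell (33 and 0 adjusted over the list alone), with a median of 2.50. Stmn1, Cdca3 (4.01 ± 0.15) and Prc1 (4.03 ± 0.17) were among those with the smallest p. Of 32 DNA replication and G1/S genes, 28 rose and 1 fell (29 and 1 adjusted over the list alone), among them Uhrf1 (3.93 ± 0.22) and the helicase subunit gene Mcm5 (3.05 ± 0.18). Both lists had an adjusted p = 0.198 with an estimated correlation. Hepatocyte mitogens and immediate early genes rose in 17 of 21 cases (17 adjusted over the list alone), with Egr1 at 3.87 ± 0.25 and Junb at 2.97 ± 0.21 (adjusted p = 0.122 with an estimated correlation). Of 15 p53 targets 7 rose and 2 fell (7 and 2 adjusted over the list alone), with the cell cycle inhibitor gene Cdkn1a at 3.26 ± 0.22 (adjusted p = 0.285 with an estimated correlation). Without the knockout vehicle array the p53 list had an adjusted p = 0.0538.

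Of 28 monocyte and macrophage genes 16 rose and 0 fell (18 and 0 adjusted over the list alone), with Cd63 at 3.98 ± 0.21 and the lectin gene Lgals3 at 2.07 ± 0.19 (adjusted p = 0.255 with an estimated correlation). Of 9 neutrophil genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), with S100a8 at 2.55 ± 0.39 and Lcn2, which is also on the acute phase list. Of 25 acute phase genes 11 rose and 2 fell (12 and 2 adjusted over the list alone), with Saa1 at 3.33 ± 0.29 and Saa2 at 3.17 ± 0.24. Both lists had an adjusted p = 0.255 with an estimated correlation.

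Of 30 collagen, matrix and stellate cell genes 16 rose and 4 fell (16 and 5 adjusted over the list alone). The smooth muscle actin gene Acta2 rose by 3.66 ± 0.24 and the protease inhibitor gene Timp1 by 3.35 ± 0.22, and Lrat, a retinoid enzyme gene of quiescent stellate cells, was lower at -1.13 ± 0.18 (adjusted p = 0.316 with an estimated correlation for the list). Of 6 cholangiocyte and progenitor genes 4 rose (5 adjusted over the list alone), with Afp and Gpc3 (1.09 ± 0.17) as examples (adjusted p = 0.198 with an estimated correlation for the list). Gpc3 was not well above background on the vehicle arrays, so its value is a fitted one and no bound. Without the wild-type vehicle array neither the collagen list (median 0.19, adjusted p = 0.870) nor the cholangiocyte and progenitor list (median 0.28, adjusted p = 0.127) nor Gpc3 (0.17, adjusted p = 0.630) passed. Without the knockout vehicle array these values were 1.05, 1.60 and 2.01. Each such fit holds the response of 1 genotype, the knockout in the former case and the wild type in the latter.

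Of 23 pericentral hepatocyte genes 19 fell and 1 rose (19 and 1 adjusted over the list alone), including Slc1a2 and the glutamine synthetase gene Glul at -2.97 ± 0.17 (adjusted p = 0.198 with an estimated correlation). Of 35 P450 genes 25 fell and 2 rose (26 and 3 adjusted over the list alone), with Cyp2b13 at -2.81 ± 0.22 and Cyp2b9 at -1.71 ± 0.18 (adjusted p = 0.303 with an estimated correlation). Both lists hold Cyp1a2 and other P450 genes. Of 24 periportal genes 12 fell and 3 rose (12 and 3 adjusted over the list alone), with the gluconeogenic gene Pck1 at -1.98 ± 0.24, while the apolipoprotein gene Apoa4 rose by 3.13 ± 0.18 (adjusted p = 0.482 with an estimated correlation). Of 20 bile acid genes 12 fell and 2 rose (12 and 3 adjusted over the list alone), with Cyp7b1 at -2.98 ± 0.19 and Cyp27a1 at -1.87 ± 0.17 (adjusted p = 0.300 with an estimated correlation). Without the wild-type vehicle array Cyp7b1 was -1.75. The periportal list did not pass without the knockout vehicle array (adjusted p = 0.203) or with fry (adjusted p = 0.0971).

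Of 20 fatty acid synthesis genes 10 fell and 0 rose (13 and 0 adjusted over the list alone), with Thrsp at -3.40 ± 0.22 and Acss2 at -2.44 ± 0.27 (adjusted p = 0.255 with an estimated correlation). Of 18 cholesterol synthesis genes 10 fell and 0 rose (10 and 1 adjusted over the list alone), with Tm7sf2 at -2.48 ± 0.20 and Sc5d at -1.87 ± 0.17 (adjusted p = 0.300 with an estimated correlation). Of 14 fasting and feeding genes 8 fell and 1 rose (10 and 2 adjusted over the list alone), with Igfbp1, which rose, at 2.72 ± 0.27 (adjusted p = 0.198 with an estimated correlation). Without the knockout vehicle array the cholesterol list had a median of 0.051 (adjusted p = 0.645) and the fasting and feeding list one of -0.36 (adjusted p = 0.281). Without the wild-type vehicle array Igfbp1 was 1.78.

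Of 15 male-high liver genes 9 fell and 1 rose (10 and 1 adjusted over the list alone), with Hsd3b5 and Cyp7b1 as examples, and of 10 female-high genes 7 fell and 1 rose (9 and 1 adjusted over the list alone), with Hao2 at -1.98 ± 0.23. The sex-biased lists were fixed as a check of the samples, but whether sex was matched between the groups was not tested. Of 5 genes on the B and plasma cell list 5 fell (5 adjusted over the list alone), with Tnfrsf17 at -1.19 ± 0.16 and H2-Eb1 at -1.27 ± 0.20. All but Tnfrsf17 are antigen presentation genes, which other cells express too. These 3 lists had an adjusted p = 0.198 with an estimated correlation. Without the knockout vehicle array neither the B and plasma cell list (adjusted p = 0.0538) nor H2-Eb1 (-0.73, adjusted p = 0.0780) nor Cd74 (-0.04, adjusted p = 0.938) passed, and without the wild-type one H2-Aa did not (0.09, adjusted p = 0.805). Nor did that list without a probe filter (adjusted p = 0.0706) or with detection on 3 of 8 arrays (adjusted p = 0.0656). In all, 19 of 32 lists passed with the preset correlation, 23 with fry and 0 with the estimated correlation. The number of changed genes was 1747 without the knockout vehicle array.

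The other 13 lists did not pass for CCl4 with camera. With fry 5 of them did, those of ER stress and type 2 response (both adjusted p = 0.0347), efferocytosis (0.000601) and adipose, mesothelium and gallbladder (0.0495) as higher and that of the circadian clock (0.0067) as lower. Members that rose and fell numbered 7 and 4 of 25 for NRF2 targets, 7 and 2 of 19 for ER stress (8 and 2 adjusted over the list alone) and 2 and 6 of 23 for fatty acid oxidation (2 and 7 adjusted over the list alone). They numbered 3 and 0 of 14 for Kupffer cells (0 and 0 adjusted over the list alone), 6 and 1 of 17 for efferocytosis, 1 and 1 of 3 for T and NK cells, and 4 and 4 of 21 for sinusoidal endothelium. They numbered 1 and 5 of 8 for erythroid genes, 2 and 1 of 3 for adipose, mesothelium and gallbladder, 7 and 5 of 28 for interferon-stimulated genes and 1 and 5 of 12 for the circadian clock. Neighbours of the Il4 and Il13 locus numbered 2 and 3 of 18 (1 and 2 adjusted over the list alone). Adjustment over the list alone left the other counts as they were. The NRF2 list had a median of -0.08, a mean of 0.06 and a test that pointed down, and the interferon list had a median of -0.014, a mean of -0.0033 and a test that pointed up.

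Type 2 response genes did not pass as a list for CCl4 (adjusted p = 0.218), with 3 of 9 that rose and 1 that fell (4 and 1 adjusted over the list alone). The list has 33 members on the array, of which 9 were measured. With fry the list passed as higher (adjusted p = 0.0347). The receptor antagonist gene Il1rn rose by 1.97 ± 0.26, Tgm2 by 0.70 ± 0.18 and Cish by 0.57 ± 0.20, and Igf1 was lower at -0.60 ± 0.16. Without the wild-type vehicle array Tgm2 was 0.45 (adjusted p = 0.200) and Cish 2.17, and without the knockout vehicle array Igf1 was -0.44 (adjusted p = 0.171) and Cish -1.05 (adjusted p = 0.0210). Cish also did not pass with any of 4 CCl4 arrays left out (highest adjusted p = 0.0808) or in 6 other alternatives (highest adjusted p = 0.433), and Igf1 did not with replicate as a block (adjusted p = 0.112). Values that did not pass were -0.02 ± 0.19 for Arg1, -0.11 ± 0.23 for Ccl24, 0.70 ± 0.26 for Clec7a, 0.30 ± 0.17 for Il13ra1 and 0.02 ± 0.19 for Mrc1. Clec7a did not pass in 12 of 19 alternatives but did in the others, among them at 0.87 without wild-type CCl4 replicate 1 (adjusted p = 0.00478), at 0.79 with median scaling (adjusted p = 0.0182) and in the other direction, at -0.56, with all probes (adjusted p = 0.0187).

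**Figure D1:**
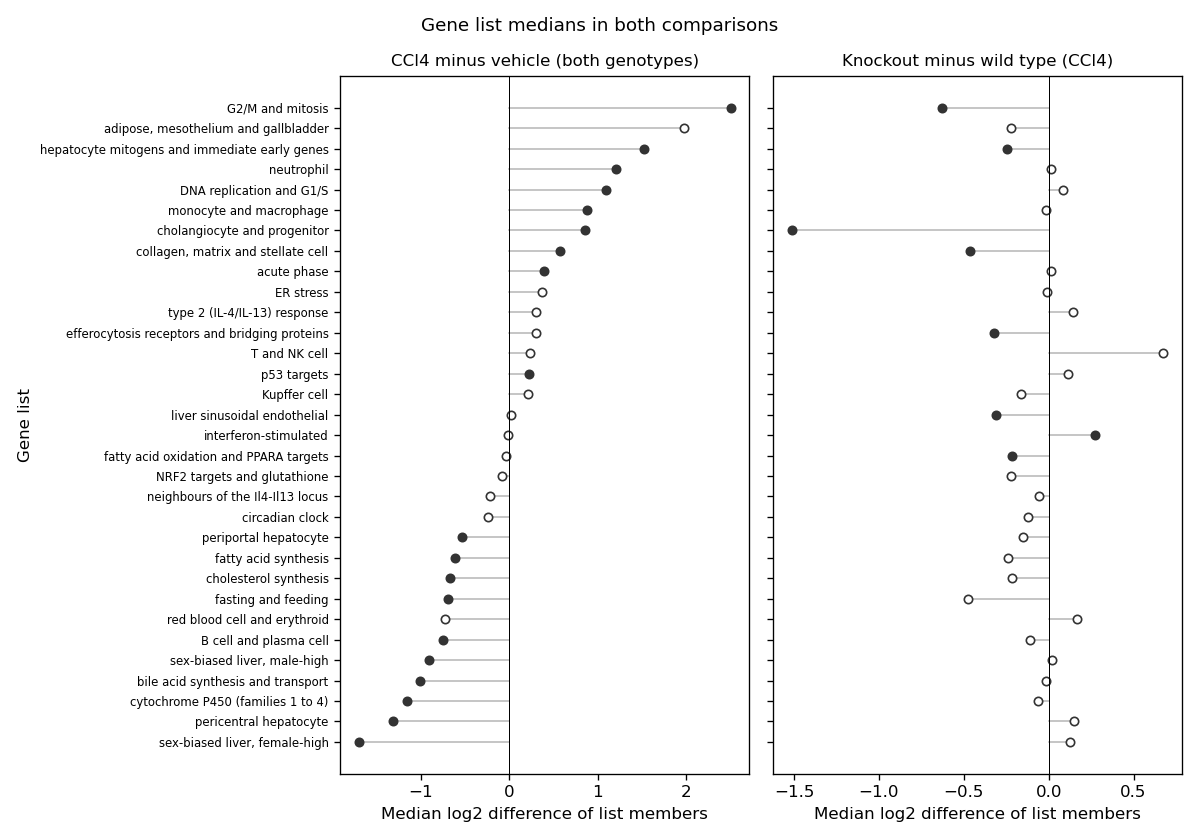
Median log2 difference of each of the 32 tested gene lists, for CCl4 minus vehicle as the mean of both genotypes and for knockout minus wild type after CCl4; filled points passed camera with a preset correlation and open points did not. G2/M and mitosis genes had a median of 2.50 for CCl4 and of -0.63 between genotypes, and 0 lists passed with an estimated correlation.

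In each genotype separately, 3 CCl4 arrays stood against 1 vehicle array. CCl4 changed 1742 genes in wild type (897 up, 845 down) and 1885 in the knockout (948 up, 937 down). The deposited values gave 1070 up and 379 down in wild type and 887 and 518 in the knockout, and median scaling gave 1149 and 650 in wild type, where these settings moved the median of all genes by 0.23 and 0.11. Afp rose at least 71.8-fold in wild type and at least 11.2-fold in the knockout, and its responses differed (adjusted p = 0.0258). That difference did not pass in 4 of 16 alternatives (highest adjusted p = 0.126), and it rests on vehicle arrays where Afp was not above background. Lcn2 rose by 6.40 ± 0.28 in wild type and by 4.44 ± 0.28 in the knockout, a difference that did not pass (adjusted p = 0.0616). Mitosis genes rose in 30 of 33 cases in wild type and 31 of 33 in the knockout (31 and 31 adjusted over the list alone), with medians of 2.81 and 2.06 (adjusted p = 0.227 and 0.268 with an estimated correlation).

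Collagen, matrix and stellate cell genes rose in 19 and fell in 1 of 30 cases in wild type (21 and 2 adjusted over the list alone, adjusted p = 0.254 with an estimated correlation). In the knockout 3 rose and 7 fell (4 and 7 adjusted over the list alone), and the list did not pass (adjusted p = 0.864). The lone knockout vehicle array was itself higher than the wild-type one for this list, by a median of 0.40. That difference enters the gap between the 2 responses in full. In wild type 16 of 32 lists passed, and in the knockout 18, with 0 in either under an estimated correlation. In wild type the NRF2 list had a median of -0.13 and a mean of 0.20, the interferon list 0.13 and -0.04 and the cholesterol list 0.05 and -0.06, and in the knockout the fatty acid oxidation list had 0.13 and -0.23 and the Kupffer cell list -0.05 and 0.05. Across the 7257 genes, which are not independent replicates, the 2 responses had a Pearson correlation of 0.690 and a Spearman correlation of 0.555. Of 2740 genes called in either genotype 2288 (83.5%) had the same sign, and 877 of the 887 called in both did.

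The genotypes were then compared after CCl4 (3 knockout against 3 wild-type arrays). Lower in the knockout were the fetal liver gene Afp by a log2 difference of -2.75 ± 0.22 (SE) and the heparan sulfate proteoglycan gene Gpc3 by -2.50 ± 0.17 (at least 4.15-fold, not well above background on the knockout arrays). The growth factor gene Igf2 was lower by -2.47 ± 0.28 and detected on 1 of 3 knockout arrays. Of the major urinary protein genes, Mup2 was at least 276-fold higher and not well above background on the wild-type CCl4 arrays, Mup20 differed by 3.06 ± 0.26 and Mup6 by 2.61 ± 0.20, although these genes are near-identical copies whose probes can cross-hybridise. The other 2 measured genes of this family, named after their values were seen, were at 0.88 ± 0.17 for Mup21 and 0.61 ± 0.22 for Mup5 (adjusted p = 0.116). Zhx2, a transcriptional repressor of fetal liver genes, was at least 1.71-fold higher in the knockout and not well above background on the wild-type arrays.

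In all, 213 genes were higher and 261 lower in the knockout (limma with Benjamini-Hochberg adjustment), 65 and 63 of them by at least 1 on the log2 scale. Without wild-type CCl4 replicate 3 more were higher (454) than lower (351). Also higher were the neutrophil protease gene Prtn3 (2.78 ± 0.36, detected on 2 of 3 wild-type arrays), the carbonic anhydrase gene Car3 (2.24 ± 0.50), Ugt3a1 (2.21 ± 0.19, detected on 1 of 3 wild-type arrays) and the T cell kinase gene Zap70 (2.13 ± 0.23). Also lower were the dynein gene Dnaic1 (-2.95 ± 0.27), Depp1 (-2.48 ± 0.36), the imprinted adaptor gene Grb10 (-2.26 ± 0.18), the lipoprotein lipase gene Lpl (-2.22 ± 0.18) and Sult1c2 (-2.20 ± 0.27). Car3 did not pass with any of 5 of the 6 CCl4 arrays left out (highest adjusted p = 0.102), nor with a trended robust eBayes (adjusted p = 0.163). Without a probe filter Car3, Prtn3 and Depp1 did not pass (adjusted p = 0.164, 0.0566 and 0.0646).

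**Figure D2:**
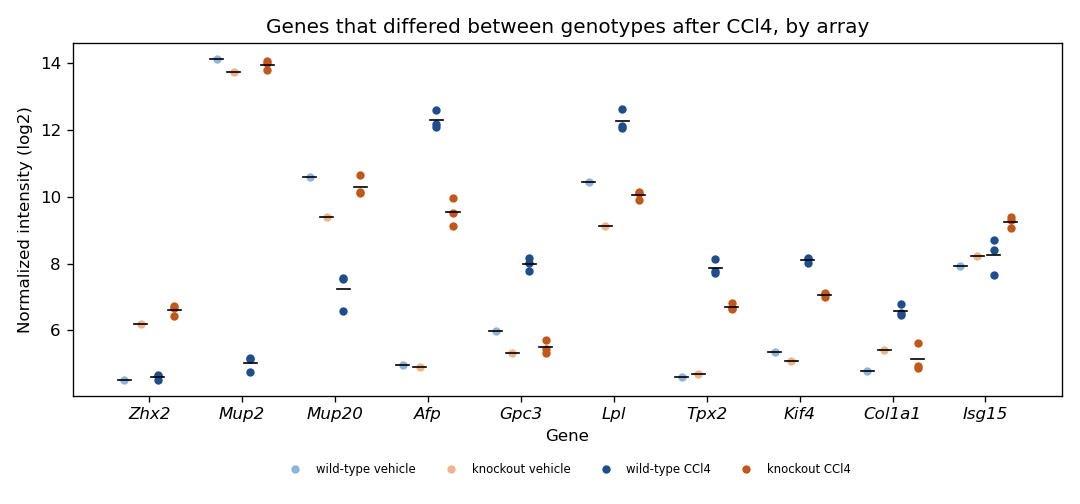
Normalized log2 intensity of 10 genes on each of the 8 arrays, with points for arrays and bars for group means (1 vehicle and 3 CCl4 arrays per genotype). Zhx2 was detected on the 4 knockout arrays and on 0 of the 4 wild-type arrays, and Mup2 was 14.12 on the wild-type vehicle array and 5.03 on average on the wild-type CCl4 arrays.

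Mitosis genes were lower in the knockout after CCl4: 14 of 33 were lower and 0 higher (22 and 0 adjusted over the list alone), with a median of -0.63. Kif4 was at -1.04 ± 0.15, Tpx2 at -1.16 ± 0.16, Ckap2l at -1.36 ± 0.20 and Kif2c at -1.22 ± 0.18 (adjusted p = 0.332 with an estimated correlation for the list). DNA replication and G1/S genes did not pass as a list, with 2 higher and 1 lower of 32 (2 and 1 adjusted over the list alone) and a median of 0.08. Hepatocyte mitogens and immediate early genes were lower in 2 of 21 cases (5 adjusted over the list alone), Egr1 (-1.31 ± 0.25) and Gadd45b (-0.87 ± 0.19), with an adjusted p = 0.322 with an estimated correlation. That list did not pass without wild-type CCl4 replicate 3 (adjusted p = 0.103) or knockout CCl4 replicate 2 (adjusted p = 0.136), nor Egr1 without knockout CCl4 replicate 1 (adjusted p = 0.0607), nor Gadd45b with any of 4 CCl4 arrays left out (highest adjusted p = 0.0826). The list also did not pass with median scaling, the deposited values, no probe filter or fry (adjusted p = 0.0672, 0.266, 0.0801 and 0.0907), nor Egr1 and Gadd45b without a probe filter (adjusted p = 0.0988 and 0.0889).

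Of 30 collagen, matrix and stellate cell genes 7 were lower (16 adjusted over the list alone), with a median of -0.47, the fibrillar collagen gene Col1a1 at -1.45 ± 0.21 and the gelatinase gene Mmp2 at -1.13 ± 0.19. Of 21 sinusoidal endothelial genes 4 were lower (5 adjusted over the list alone), with Eng at -0.75 ± 0.16 and the hyaluronan receptor gene Lyve1 at -0.84 ± 0.19. The cholangiocyte and progenitor list had 3 lower of 6 (4 lower and 1 higher adjusted over the list alone), and these were Afp, Gpc3 and Igf2, which fetal hepatocytes express. These 3 lists had an adjusted p = 0.322 with an estimated correlation. Without a probe filter the cholangiocyte and progenitor list did not pass (median -0.070, adjusted p = 0.0801). Eng did not pass with any of 3 CCl4 arrays left out (highest adjusted p = 0.0901), nor Lyve1 with any of 4 (highest adjusted p = 0.109). Without a probe filter neither these 2 (adjusted p = 0.0520 and 0.104) nor Mmp2 (adjusted p = 0.0590) passed.

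Fatty acid oxidation and PPARA target genes were lower in 6 of 23 cases (7 adjusted over the list alone), with Cyp4a14 at -2.16 ± 0.27 and the peroxisomal enzyme gene Ehhadh at -0.82 ± 0.16 (adjusted p = 0.332 with an estimated correlation for the list). Efferocytosis genes were lower in 2 of 17 cases (6 lower and 1 higher adjusted over the list alone), C1qb (-0.61 ± 0.16) and Stab2 (-0.59 ± 0.16). Of these Stab2 is also on the sinusoidal endothelial list, which was lower, and C1qb on the Kupffer cell list, which did not pass (median -0.17), so these 2 do not single out efferocytosis. Of 28 interferon-stimulated genes 5 were higher and 0 lower (7 and 0 adjusted over the list alone), with Ifi27 at 0.81 ± 0.14 and the immunoproteasome gene Psmb9 at 0.88 ± 0.18; the list also passed in the deposited values (adjusted p = 0.00162), where its median was -0.064 and that of all genes -0.37. Both lists had an adjusted p = 0.322 with an estimated correlation. Leaving out 1 CCl4 array ended the calls of the efferocytosis list for 3 of the 6 arrays (highest adjusted p = 0.0641), of Ehhadh for 4 (0.0741), of C1qb for 5 (0.139), of Stab2 for 6 (0.153), of Ifi27 for 2 (0.0535) and of Psmb9 for 3 (0.0818). Without a probe filter C1qb, Stab2, Psmb9 and the efferocytosis list did not pass (adjusted p = 0.0863, 0.0786, 0.0672 and 0.0520). The deposited values, with their shift of all genes, ended the calls of Psmb9 (adjusted p = 0.0813), the efferocytosis list (0.0675) and the fatty acid oxidation list (0.0506). Detection on 3 of 8 arrays ended those of C1qb and Stab2 (adjusted p = 0.0576 and 0.0594), as did replicate as a block (adjusted p = 0.0633 and 0.0792). In all 8 of 32 lists passed with the preset correlation, 8 with fry and 0 with the estimated correlation. Of the 8, 1 was higher and 7 lower in the knockout, against 3 and 6 with median scaling, 4 and 4 in the deposited values, 2 and 6 with fry and 5 and 7 without wild-type CCl4 replicate 2.

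Type 2 response genes did not pass between genotypes (limma): 0 of 9 measured genes were called (0 adjusted over the list alone), and the list had a median of 0.14 (adjusted p = 0.478). The list has 33 members on the array, and those beyond the 9 did not pass the probe filter and were not tested. Arg1 and Igf1 are also on the periportal list, Mrc1 on the sinusoidal endothelial list and Il1rn on the acute phase list. The result therefore does not show that the type 2 response was unchanged. Il13ra1, a chain of the IL-13 receptor, was at 0.54 ± 0.17 (adjusted p = 0.0852). The other values were -0.08 ± 0.19 for Arg1, 0.0061 ± 0.23 for Ccl24, 0.33 ± 0.20 for Cish, 0.31 ± 0.26 for Clec7a, -0.27 ± 0.16 for Igf1, 0.33 ± 0.26 for Il1rn, 0.14 ± 0.19 for Mrc1 and -0.02 ± 0.18 for Tgm2.

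The remaining lists did not pass between genotypes with camera, while the male-high list passed as higher with fry (adjusted p = 0.0118). Members higher and lower in the knockout numbered 1 and 0 of 15 for p53 targets (2 and 1 adjusted over the list alone), 0 and 3 of 19 for ER stress (0 and 3), and 0 and 1 of 24 for periportal genes (0 and 0). They numbered 2 and 2 of 35 for P450 genes (3 and 7 adjusted over the list alone) and 3 and 2 of 20 for bile acid genes (3 and 4). They numbered 2 and 2 of 20 for fatty acid synthesis (3 and 5 adjusted over the list alone), 1 and 4 of 14 for fasting and feeding (2 and 5), 0 and 1 of 28 for monocytes and macrophages (1 and 3) and 1 and 1 of 14 for Kupffer cells (2 and 3). They numbered 1 and 0 of 3 for T and NK cells (2 and 0 adjusted over the list alone), 0 and 2 of 25 for acute phase genes (0 and 3), 4 and 2 of 15 for male-high genes (6 and 2) and 2 and 0 of 10 for female-high genes (3 and 1). None was called, adjusted either way, among 25 NRF2 targets, 23 pericentral, 18 cholesterol synthesis, 9 neutrophil, 5 B and plasma cell, 8 erythroid, 3 adipose, mesothelium and gallbladder and 12 circadian genes and 18 neighbours of the Il4 and Il13 locus. The pericentral list passed as higher without wild-type CCl4 replicate 2 (median 0.29, adjusted p = 0.0253). The acute phase list had a median of 0.01, a mean of -0.07 and a test that pointed down, and the neighbours had -0.06, -0.02 and a test that pointed up.

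The 200 genes that CCl4 raised most had a median difference of -0.18 between genotypes (120 lower and 80 higher in the knockout). By limma's camera this gave an adjusted p = 0.0029 over the 2 sets, and an adjusted p = 0.422 with an estimated correlation. Without knockout CCl4 replicate 2 the median was -0.11 and the set did not pass (adjusted p = 0.0792). The 200 genes that it lowered most had a median of -0.03 (adjusted p = 0.965). Without wild-type CCl4 replicate 2 this set passed in the other direction, with a median of 0.11 (124 higher and 76 lower, adjusted p = 0.000261). The number of genes called between genotypes was 140, 295 and 805 without wild-type CCl4 replicate 1, 2 and 3, and 122, 129 and 121 without knockout CCl4 replicate 1, 2 and 3. Median scaling, which moved the median difference of all genes by -0.16, gave 171 higher and 704 lower genes, and the deposited values, which moved it by -0.35, gave 57 and 1251.

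The response to CCl4 differed between genotypes for 26 genes, 13 with a more positive and 13 with a more negative response in the knockout, and 1448 genes had an unadjusted p under the threshold. Median scaling gave 14 and 25. Mup2 had an interaction of at least 8.48: it was 14.12 on the wild-type vehicle array, 5.03 on average on wild-type CCl4 arrays, 13.75 on the knockout vehicle array and 13.96 on knockout CCl4 arrays. Mup20 (4.27 ± 0.52), the cytokine signalling inhibitor gene Cish (3.23 ± 0.40) and the oxysterol hydroxylase gene Cyp7b1 (2.45 ± 0.38) had the same direction. The repressor gene Bcl6 (-2.90 ± 0.41), Afp (-2.69 ± 0.44) and the liver pyruvate kinase gene Pklr (-2.21 ± 0.33) had the opposite one. The values of Afp and Pklr are fitted ones and no bounds, since Afp was not above background on either vehicle array, nor Pklr on any wild-type array. Any difference between the lone vehicle arrays enters these values in full. For Bcl6, wild type and knockout were 7.73 and 10.28 on vehicle and 7.99 and 7.64 on average after CCl4. For Cish they were 9.91 and 7.01 on vehicle and 8.87 and 9.19 after CCl4. These 2 interactions thus lay mostly between the vehicle arrays, unlike that of Mup2. Cyp7b1 and Afp did not pass without wild-type CCl4 replicate 1 (adjusted p = 0.0588 and 0.0619) or knockout CCl4 replicate 1 (adjusted p = 0.0542 and 0.0606), and the count was 14, 65 and 128 without knockout CCl4 replicate 1, wild-type CCl4 replicate 2 and wild-type CCl4 replicate 3. More positive and more negative responses then numbered 9 and 5, 27 and 38, and 95 and 33. Without a probe filter only Mup2 passed. With the deposited values Cyp7b1, Bcl6, Afp and Pklr did not pass (adjusted p = 0.0921, 0.0571, 0.0859 and 0.0777).

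Of 32 lists 10 passed for the interaction, 4 with fry and 0 with an estimated correlation. The 4 that passed fry were cholangiocyte and progenitor genes (median -1.48, adjusted p = 0.399 with an estimated correlation), fasting and feeding genes (-0.94, 0.382), male-high genes (0.72, 0.514) and efferocytosis genes, whose median of -0.35 did not pass camera. Cholesterol synthesis genes had a median of -1.03 with 2 of 18 called, both lower (9 adjusted over the list alone, adjusted p = 0.399 with an estimated correlation). Fatty acid synthesis genes had a median of -0.72 with 1 of 20 called (4 lower and 1 higher adjusted over the list alone, adjusted p = 0.514 with an estimated correlation). Erythroid genes had a median of 1.24 with 1 of 8 called, which was higher (5 adjusted over the list alone, adjusted p = 0.514 with an estimated correlation). Periportal genes (median -0.39, adjusted p = 0.724 with an estimated correlation) and sinusoidal endothelial genes (median -0.27, adjusted p = 0.514 with an estimated correlation) had 0 called. Collagen, matrix and stellate cell genes had a median of -0.80 with 0 members called (10 lower adjusted over the list alone, adjusted p = 0.399 with an estimated correlation). Mitosis genes had a median of -0.78 with 0 called (10 lower and 1 higher adjusted over the list alone, adjusted p = 0.514 with an estimated correlation).

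The vehicle arrays, 1 per genotype, differed by at least 1 on the log2 scale for 288 genes, 147 higher and 141 lower in the knockout, with no replicate to set this against. Lipid synthesis genes were higher on the knockout array, with list medians of 0.81 for cholesterol synthesis and 0.64 for fatty acid synthesis, both at percentile 100 of random lists. The collagen list had a median of 0.40 (percentile 100) and erythroid genes one of -1.02 (percentile 0). As 16 of the 32 lists lay outside the middle 95% of random lists, these percentiles do not single out any of them. The deposited values gave 164 higher and 464 lower genes.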

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

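The tests of the MHC region, of lipid synthesis and of subsets of the genes in the vehicle pair were chosen after the results were seen; the splits and the vehicle pair over all called genes were not.

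The response to CCl4 differed between genotypes, by a test of the difference itself, for 26 genes. The 16 named ones had interactions of 9.30 for Mup2, 4.27 for Mup20, 3.39 for Abhd16a, 3.38 for Radx, 3.23 for Cish, 3.14 for Mup6, 2.45 for Psmb9, 2.45 for Cyp7b1, -2.90 for Bcl6, -2.69 for Afp, -2.67 for Rgs16, -2.36 for H2-Q5, -2.21 for Pklr, -2.17 for H2-K1, -2.15 for Nsdhl and -2.05 for Tubb2b. With a group that was not above background held at its floor, Mup2 had at least 8.48, Radx at least 2.09 and Rgs16 a value of -1.48 or lower, and no bound could be set for Afp and Pklr. Leaving out 1 CCl4 array ended the call of H2-K1 for 2 of the 6 arrays (highest adjusted p = 0.0561), of Nsdhl for 4 (0.0808), of Tubb2b for 3 (0.0687), of Cyp7b1 for 2 (0.0588) and of Afp for 2 (0.0619). With the mean of probes Tubb2b and Nsdhl did not pass (adjusted p = 0.262 and 0.0713), nor did Nsdhl with detection on 3 of 8 arrays (0.0526). Without a probe filter 15 of the 16 did not pass, all but Mup2 (highest adjusted p = 0.126). With the deposited values 11 did not (highest adjusted p = 0.0988), all but Mup2, Mup20, Radx, Cish and Mup6.

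These values rest on 1 vehicle array per genotype. In the vehicle pair the knockout differed from the wild type by -3.31 for Abhd16a, -2.90 for Cish, -1.93 for Cyp7b1 and 2.55 for Bcl6. For these genes that was most of the interaction. For Mup2, Mup20 and Mup6 the vehicle difference was -0.38, -1.21 and -0.53, the smaller part. A swap of the vehicle labels was therefore tested. The planned test gave a share under 50%, as a swap would: of the 474 genes called between genotypes after CCl4, 208 (43.9%, exact 95% interval 39.4 to 48.5%) had the same direction in the vehicle pair, an interval that treats co-expressed genes as independent. Zhx2, named beforehand, pointed against one, since it was undetected on the wild-type vehicle array (detection p of 0.890) and detected on the knockout one (0.0075). After the planned value was seen, other sets were tried: 73 of 128, 29 of 39 and 14 of 18 genes with differences of at least 1, 1.5 and 2 had the same direction, and among genes that CCl4 did not change 81 of 207, 23 of 40, 10 of 11 and 5 of 5 did with no minimum and at the same 3 sizes. At 1.5 and 2, the exact 95% intervals of all called genes lay above 50% (57.87 to 86.96% and 52.36 to 93.59%), against a swap. With no minimum, the interval of the genes that CCl4 did not change lay below 50% (32.44 to 46.14%), as the planned one did. The sets thus point both ways, and those of the largest differences were not planned. All rest on 1 vehicle array per genotype, so a swap may still apply and the 2 readings cannot be told apart here.

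Other explanations concern parts of the 26 genes. A different feeding or lipid synthesis state of the vehicle animals may account for Pklr and Nsdhl: without the interaction genes both lipid synthesis lists lay at percentile 100 of random lists in the vehicle pair. As 16 of the 32 lists lay outside the middle 95%, that percentile does not single out lipid synthesis, and this stays open. Another MHC haplotype on the wild-type vehicle array is a candidate explanation for Abhd16a, Psmb9, H2-K1 and H2-Q5: 14% of 50 genes in that region of chromosome 17 differed by at least 1 in the vehicle pair, against 3.90% elsewhere (Fisher's exact p = 0.00332). Without the interaction genes, which prompted that test, Fisher's exact p was 0.242, so it stays open. A biological difference between the genotypes stays open as well and was not tested apart from these.

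Of the 10 splits of the 6 CCl4 arrays into 3 and 3, 1, the real one, called 474 genes between genotypes, and the highest of the others called 0. Each other split mixes the genotypes within its groups, so a genotype difference adds to its residual spread and lowers its calls. Its 0 is therefore no measure of what chance gives. Also, 10 splits are too few for a share under 0.05. Groups did not overlap for 2202 of 7257 genes (30.3%, where chance gives 10% for a single gene), 473 of them among the 474. A call nearly implies no overlap, so the 473 add nothing. Genes vary together across arrays, so the 30.3% is no test either.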

How the results depend on the processing

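Alternatives were set before the data were examined, except the estimated correlation, fry and the adjustment over the 2 sets for CCl4-responsive genes, which were added after seeing the data. The genes called between genotypes after CCl4 (474) numbered 875 with median scaling and 1308 with the deposited values, which both shift all genes, 109 without a filter, which tests more genes, and 128 with a log2 difference of at least 1. That minimum left 897 genes for CCl4 as the mean of both genotypes, 1062 in wild type and 1122 in the knockout. The shift of all genes follows the raw intensities of the CCl4 arrays. Their 75th percentiles were 198 to 239 in wild type and 170 to 176 in the knockout. Quantile normalization removes such a difference, which goes with the genotype. Whether it was technical or biological was not tested. The 26 interaction genes became 41 with normexp, 46 without background correction, 10 with the deposited values, 1 without a filter and 76 with a trended robust eBayes; the cause was not tested. With 1 array left out, where a group of 1 or 2 is assumed to vary like the others, counts ran from 121 to 805 between genotypes, from 1747 to 3008 for CCl4, from 1334 to 2024 in wild type, from 1431 to 2136 in the knockout and from 14 to 128 for the interaction. The replicate number as a block gave 427, 1922, 1383, 1353 and 40 genes in the same order. The lowest left-out count for CCl4 came from a fit without a vehicle array, which holds the response of 1 genotype alone. Same-numbered CCl4 arrays did not deviate together (correlations of -0.12, -0.11 and -0.013), and no array correlated best with its own number. Chip as a block was not run, since the files give no chip.

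With an estimated correlation 0 lists passed between genotypes and 0 for CCl4, and with arrays left out 7 to 12 and 16 to 20 did. The CCl4-raised set had its median of -0.18 with an adjusted p = 0.422 under an estimated correlation, and ran from -0.30 to -0.11 with arrays left out. Adjusted over the 2 sets it also did not pass without knockout CCl4 replicate 2 (adjusted p = 0.0792) or for 500 genes (adjusted p = 0.0679). With fry the unadjusted p was 0.0792 for 200 genes, 0.184 for 500 and 0.0209 for 100. The CCl4-lowered set had -0.31 with the deposited values, where it passed, 0.0039 with the mean of probes, 0.0045 for 100 genes, and -0.12 to 0.11 with arrays left out, where the 0.11, without wild-type CCl4 replicate 2, passed in the other direction (adjusted p = 0.000261). The correlation of the responses ran from 0.640 to 0.713. The vehicle pair had 108 genes with normexp and 628 with the deposited values. The undetected Il4 differed by -0.15 between genotypes, by -0.34 in raw intensities and by 0 in the deposited values.

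Signs turned mostly for values near 0 that had not passed. Median scaling and the deposited values shift all genes, to medians of -0.17 and -0.37 between genotypes, so a turn of sign there need not be one relative to other genes. Each list named below for these settings stayed above that median. Between genotypes, median scaling gave -0.13 for the DNA replication list, 0.021 for Arg1, -0.18 for Ccl24 and -0.019 for Mrc1. The deposited values gave -0.31 for DNA replication, -0.064 for interferon, -0.14 for type 2 and -0.11 for pericentral genes, -0.42 for Ccl24, -0.19 for Mrc1, -0.035 for Cish, -0.054 for Il1rn and -0.063 for Clec7a. With arrays left out the type 2 list ran from -0.021 to 0.30, Arg1 from -0.18 to 0.12, Ccl24 from -0.18 to 0.23, Mrc1 from -0.045 to 0.30, Clec7a from -0.021 to 0.53 and Tgm2 from -0.17 to 0.073. For CCl4, Ccl24 was 0.042 with median scaling and 0.15 with the deposited values, Clec7a -0.56 with all probes, where it passed (adjusted p = 0.0187), and Mrc1 -0.090 with the block. With arrays left out the cholesterol list ran from -1.16 to 0.051, Arg1 from -0.22 to 0.19, Ccl24 from -0.30 to 0.078, Mrc1 from -0.15 to 0.18, H2-Aa from -1.55 to 0.091, Mup2 from -9.10 to 0.21 and Cish from -1.05 to 2.17. Where a vehicle array was left out, the value is the response of the other genotype alone, so these ranges also hold genotype differences. For the interaction, Il1rn was -0.12 with median scaling and -0.25 with the deposited values and Clec7a -0.36 with all probes, and with arrays left out they ran from -0.21 to 0.29 and from -0.14 to 0.41.

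Of the genes that the naming rule takes, 24 of 69 between genotypes, 71 of 90 for CCl4 and 10 of 32 for the interaction had the same direction and side of the threshold in every alternative run. Between genotypes, the list of mitogens did not pass with median scaling, the deposited values or no filter (highest adjusted p = 0.266), nor efferocytosis with the deposited values or no filter (0.0675), fatty acid oxidation with the deposited values (0.0506) or cholangiocytes and progenitors without a filter (0.0801). In wild type alone p53 targets, efferocytosis, B and plasma cells and adipose, mesothelium and gallbladder passed fry only (highest adjusted p = 0.0449) and fatty acid synthesis camera only. In the knockout type 2, efferocytosis and cholangiocytes and progenitors passed fry only (highest adjusted p = 0.0325) and periportal genes camera only. For CCl4, B and plasma cells did not pass without or with the other filter (0.0706 and 0.0656). Normexp gave smaller values, such as -1.64 for Gpc3, -1.63 for Igf2, 1.45 for Ugt3a1, -0.81 for Col1a1, -0.61 for Mmp2, -0.87 for Ckap2l and -0.51 for Gadd45b between genotypes and 2.21 for Timp1, -0.62 for Lrat, -0.66 for Tnfrsf17 and 1.26 for Il1rn for CCl4. With their shift the deposited values gave -2.32 for Col1a1, -1.95 for Mmp2, -1.54 for Gadd45b, -1.03 for Stab2, -1.16 for Eng and -1.33 for Lyve1 between genotypes. The mean of probes gave -1.44 for Acss2 and 2.26 for Acta2 for CCl4. Low signal limits genes such as Zhx2, whose lower group lies in the background.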

Other observations

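Many lists differed between the lone vehicle arrays: 16 of the 32 lay outside the middle 95% of random lists, so the percentiles below single out none. Genes of the circadian clock had a median of 0.37 and B and plasma cell genes one of 0.90 on the knockout relative to the wild-type array, at percentiles 99.7 and 99.9 of random lists, and male-high liver genes had -0.38 (percentile 0.11). After CCl4 the clock genes Dbp and Nr1d1 had log2 changes of -2.07 ± 0.20 and -1.92 ± 0.20 as the mean of both genotypes, while the clock list did not pass with camera (adjusted p = 0.144) and passed as lower with fry (adjusted p = 0.0067). Without the knockout vehicle array Nr1d1 was -1.20.

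The tests below were chosen after the results were seen, except that of the DNA flanking the targeted genes, and the test of cell types was reworked after a first version of it, a count of lists with a median above 0, had been seen.

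Zhx2 was above background on 4 of 4 knockout arrays and on 0 of 4 wild-type arrays, vehicle included. A strain difference at Zhx2 may account for the genes it is known to regulate rather than the loss of Il4 and Il13: the BALB/cJ substrain has little Zhx2 transcript, and Afp, Gpc3, Lpl, Mup20, Mup2 and Mup6, a list written after their values were seen, were called after CCl4 in the direction that Zhx2 predicts. In the vehicle pair Lpl had the direction that Zhx2 predicts (-1.30), the Mup genes had the other one, with -1.21 for Mup20, -0.38 for Mup2 and -0.53 for Mup6, and Afp and Gpc3 were not well above background. The 2 genotypes, of Zhx2 and of the targeted genes, cannot be told apart, since by the labels they went together on all 8 arrays, although a swap of the vehicle labels stays open. DNA flanking the targeted genes cannot carry Zhx2 itself, because Zhx2 lies on chromosome 15 and these on chromosome 11. That follows from the known positions and not from the arrays. Within 10 Mb of the targeted genes 9.52% of genes were called against 6.49% elsewhere (odds ratio 1.52, Fisher's exact p = 0.227). With only 105 genes there, this does not decide whether flanking DNA adds calls.

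Of 33 mitosis genes 14 were lower in the knockout after CCl4 (adjusted p = 0.332 with an estimated correlation for the list), and 3 explanations stay open besides the loss of the cytokines. A smaller CCl4 response as a whole would need the 200 genes that CCl4 lowered most to be higher in the knockout by 0.44, a value set from medians. Their median difference was -0.03 and their mean 0.035 with an upper 95% bound of 0.60, so it could apply. Sets that CCl4 raised varied: the mitosis list had a median of -0.63 between genotypes against a response of 2.50. The 200 genes raised most had -0.18 against 2.24, DNA replication 0.08 against 1.09 and the collagen list -0.47 against 0.58. No error was set on these medians. For a smaller share of other cell types, the test assumed that macrophage genes fall along with endothelial genes. The endothelial list had a mean difference of -0.36 (95% interval -0.54 to -0.17) and the macrophage list -0.07 (-0.51 to 0.37), which cannot decide it. The collagen, matrix and stellate cell list had -0.51 (-0.82 to -0.21). A smaller share of endothelial or stellate cells without one of macrophages was not tested. A strain difference at Zhx2 cannot be told apart from the targeted genes here either, because by the labels 0 of 8 arrays had them apart.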
